A study of Mus musculus with 3 samples.

How the data were processed

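Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in HL-1 cells, a mouse cardiac muscle cell line. There were 3 libraries: an IP with an antibody against RBP2 (also KDM5A or JARID1A, a histone demethylase), an IP with an antibody against its homologue JARID2, and input DNA without an IP. Each group held 1 library. Per the labels, adapter-ligated DNA was amplified by PCR, size-selected on a gel and sequenced on a Genome Analyzer.

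The authors deposited aligned reads for each library and a peak list for each IP. Per the submitters' processing notes, the tool was Bowtie and the genome build mm9, and the version of Bowtie is not given in the sources used here. Each aligned read spanned 36 bp. The peak caller and any control it used are not given in the sources used here. Each deposited peak carries the authors' score, whose definition is not stated and which was used only to rank peaks within a list. The lowest score was 50 in both lists.

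Reads were collapsed to 1 per start position and strand, because the libraries were amplified by PCR, and 5' ends were shifted by 100 bp toward the fragment centre. Libraries were scaled by their total collapsed reads. Enrichment was the IP count plus 1 over the scaled input count plus 1. Peaks with more IP than input reads were those with an adjusted p under 0.05 in a two-sided exact conditional binomial test (Benjamini-Hochberg over the list) and a ratio of at least 2. The lists were merged into regions and the IPs compared with the same test. Shares of reads carry exact binomial (Clopper-Pearson) 95% intervals and ratios of reads exact conditional 95% intervals. Intervals of medians and strand offsets came from bootstrap resampling of peaks. All these intervals cover counting error or the choice of peaks only, since reads without molecular identifiers are not independent molecules and no library was replicated. A test on the reads of a pair of libraries compares those libraries and not the conditions. Antibody, library and sequencing run could not be told apart.

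Overlap of the lists was counted at 1 bp or more beside 1000 random placements of the JARID2 peaks on the same chromosomes. Correlations of the IPs were Spearman's rho across merged regions and across 10 kb bins with at least 20 input reads, each IP being divided by its own random part of the input reads. Peaks were called high-input where the 1 kb around their centre held more than 35 input reads, 5 times the genome median of 7. Regions were named by a fixed rule: the 5 with the highest lower bound of each ratio, among those with at least 10 IP reads and without high input. These choices were made before the data were examined, except that the 1 kb span of the high-input rule was set afterwards. A ratio against a library with 0 reads was computed against a floor of 3 counts per library.

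Alternatives fixed beforehand were all deposited reads, no shift, scaling by bins without a peak, a count of 5 added, other minimum ratios, the deeper IP thinned, the whole input in both ratios, 1 kb bins, the higher-scoring part of each list, high-input peaks left out and other definitions of overlap. A 500 bp window at each peak centre was added after windows of 100, 200, 300, 500 and 1000 bp had been looked at, because the peaks were narrower than the shift assumes. Random placements matched on input coverage, the classes of input coverage and the rule for high-coverage segments were also chosen after seeing the data. So were the simulated 1 kb windows without enrichment, the summed reads at 200 placements and the libraries thinned to equal depth before collapsing.

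The gene table at hand was in another build than the reads, so no peak was tied to a gene, and promoter shares and gene lists were not analysed here. Coordinates are mm9, counted from 1.

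The exact test was tested on simulated counts with 100 regions changed 4-fold, 100 changed 8-fold and all others unchanged. With so few changed, the adjusted threshold is stricter than in a list where most peaks are enriched. The shares recovered are therefore not the power of the test on these lists. For the merged regions the change was in the RBP2 direction only. Over the 1524 RBP2 peaks the test recovered 9% of the 4-fold and 39% of the 8-fold regions, with 0 false calls. Over the 1565 JARID2 peaks it recovered 0% and 29%, and over the 2975 merged regions, IP against IP, 26% and 65%. With 500 bp windows the shares were 45% and 86% for RBP2, 19% and 79% for JARID2, and 71% and 100% for the merged regions, with 1 false call each. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.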

Results

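The binding of RBP2 and JARID2, homologous proteins of which RBP2 is a histone demethylase and JARID2 is not, was mapped by ChIP-seq in HL-1 mouse cardiac muscle cells, with input DNA as the background. The RBP2 library held 11007905 aligned reads, the JARID2 library 6160334 and the input 18891825. After collapsing, 10692024, 5893499 and 18293844 reads were left. Each value comes from 1 library without a replicate, so differences were set against counting error only.

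Input coverage differed along the HL-1 genome. Chromosome X stood at 0.477 of the median autosome, and chromosomes 10, 13, 14 and 18 stood at 0.700, 0.691, 0.724 and 0.715. There were 8 segments of 500 kb or more with at least 3 times the median coverage of 100 kb bins, 8.4 Mb in all. The highest, on chromosome 12 from 45900001 to 46700000, had an input level of 4.81, and its RBP2 and JARID2 levels were 4.64 and 4.31. A segment on chromosome 9 from 41200001 to 43300000 had an input level of 4.07, with 4.29 for RBP2 and 3.88 for JARID2.

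**Figure D1:**
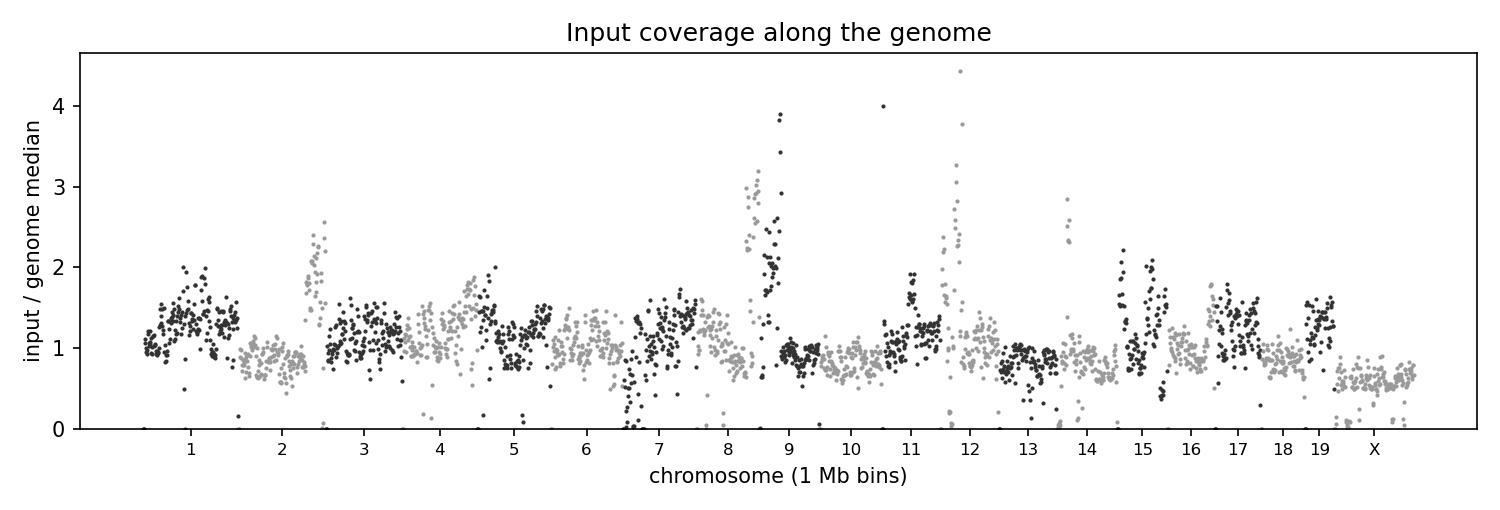
Input reads in 1 Mb bins (points), divided by the genome median, along chromosomes 1 to 19 and X in alternating shades. Chromosome X and chromosomes 10, 13, 14 and 18 lie low, and chromosomes 9 and 12 hold stretches near 4 times the median.

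The first comparison set the RBP2 IP against input. The RBP2 list held 1524 peaks with a median width of 128 bp. The highest-ranked regions were on chromosome 2 from 154617035 to 154617233, on chromosome 2 from 158593742 to 158593980, and on chromosome 12 from 81216584 to 81216909. Each of the 3 held 17 RBP2 reads and 0 input reads, 9.70-fold higher than the floor (adjusted p = 3.84e-06, exact binomial test). The lower bound of each ratio over input was 7.06. The first 2 were also JARID2 peaks, with 11 and 15 JARID2 reads, and the region on chromosome 12 held 1. Regions on chromosome 5 from 28397840 to 28398104 and on chromosome 7 from 118226408 to 118226572 followed with 15 and 13 RBP2 reads and no input read.

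Across the list, the peaks held 0.149% of RBP2 reads (0.146 to 0.151) and 0.0584% of input reads, a ratio of 2.55 (2.48 to 2.61). This ratio depended on 40 high-input peaks. Without them it was 4.54 (4.34 to 4.76). With all deposited reads kept, the 40 peaks took 1.98% of RBP2 and 2.24% of input reads, and the ratio over the whole list fell to 0.903 (0.899 to 0.908), below the input, against 4.59 for the other 1484 peaks. The top-scoring of the high-input peaks, on chromosome 17 from 39979935 to 39983339, held 3666 RBP2, 2154 JARID2 and 2782 input reads after collapsing. The median enrichment was 2.52, and 282 peaks (18.5%) passed the test against input. The count was 1413 without the shift and 956 in 500 bp windows. The list was called on these same reads, so these values are not independent evidence of binding.

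The JARID2 IP was compared with input in the same way. Its list held 1565 peaks with a median width of 142 bp, of which 1 was high-input. The highest-ranked region, on chromosome 5 from 130230808 to 130231010, held 15 JARID2 reads, 8 RBP2 reads and 0 input reads. JARID2 was 15.5-fold higher than the floor (adjusted p = 1.98e-07, exact binomial test), with a lower bound of 11.1 over input. A region on chromosome 19 from 5802497 to 5802762 held 22 JARID2, 19 RBP2 and 2 input reads, a ratio of 34.1 (8.39 to 300) over input. Regions on chromosome 2 from 154617010 to 154617226, on chromosome 5 from 28397836 to 28398068 and on chromosome 11 from 94072717 to 94072893 held 14, 13 and 13 JARID2 reads and no input read. All of these but the first were peaks in both lists.

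The JARID2 peaks held 0.110% of JARID2 reads (0.108 to 0.113) and 0.0136% of input reads, a ratio of 8.11 (7.74 to 8.50). The median enrichment was 3.03, and 702 peaks (44.9%) passed the test. Without the shift 1565 passed, and in 500 bp windows 1308. This list too was called on the reads of its own IP, so these values are not independent evidence of binding. A median of 3 IP reads and 1 input read per peak in both lists limits what can be said of any single peak. The 100 bp shift, fixed beforehand, exceeds the strand offset of the own IP at these narrow peaks (50.9 bp for RBP2 and 64.6 bp for JARID2) and moves reads out of them. Without it the shares of reads in peaks were 0.218% and 0.187%. No shifted read of the own IP lay in 188 RBP2 and 211 JARID2 peaks.

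**Figure D2:**
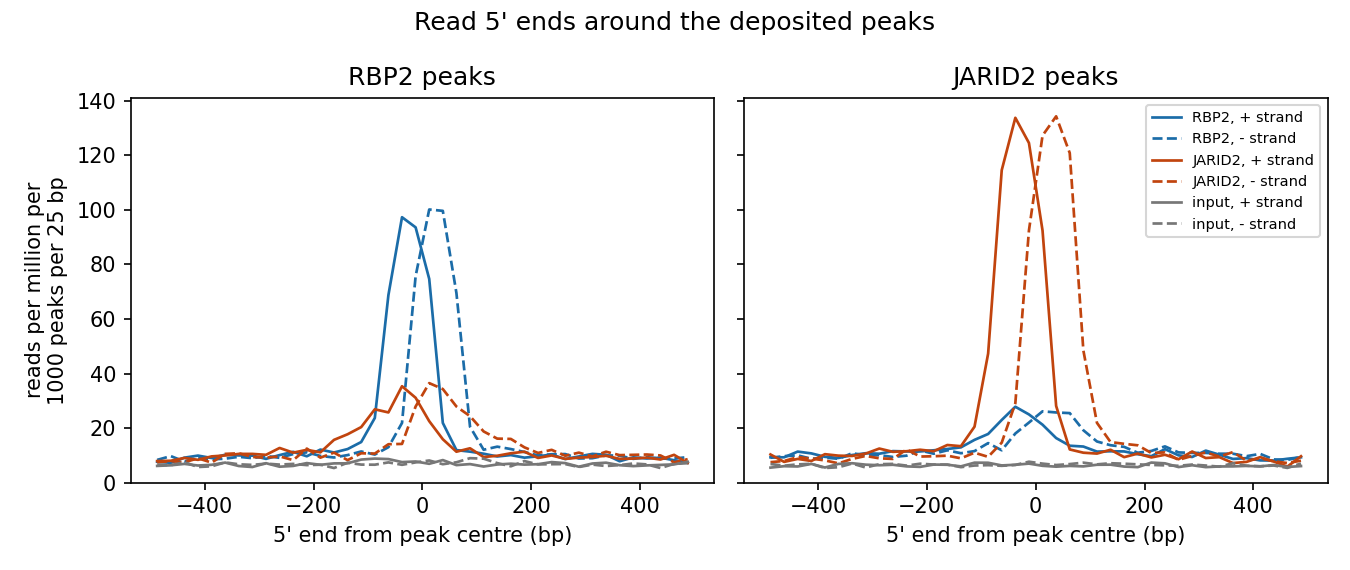
Read 5' ends per 25 bp around the centres of RBP2 (left) and JARID2 (right) peaks without high input, scaled by collapsed reads and by the number of peaks, by library (colour) and strand (solid +, dashed -). The own IP forms narrow strand peaks, 50.9 bp apart for RBP2 and 64.6 bp for JARID2, the other IP is raised at the same places, and the input is nearly flat.

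The lists were then compared with each other. Of the RBP2 peaks, 113 (7.41%) overlapped a JARID2 peak, against a mean of 0.355 and a maximum of 4 over 1000 random placements. With placements matched on input coverage the mean was 0.456 and the maximum 4. Overlap was 17.1% among the 381 RBP2 peaks with the highest scores (13.4 to 21.2) and 4.46% among the 381 with the lowest (2.62 to 7.05). For JARID2 it was 17.4% (13.8 to 21.5) and 3.06% (1.59 to 5.29). None of the 40 high-input RBP2 peaks and the 1 high-input JARID2 peak overlapped a peak of the other list. At the top-scoring high-input RBP2 peak, on chromosome 17 from 39979935, JARID2 was nevertheless 2.40 (2.27 to 2.54) over input after collapsing, and RBP2 2.25 (2.15 to 2.37). Collapsing matters at such peaks: with all deposited reads kept, RBP2 was 0.881 (0.877 to 0.886) over input at the 40 high-input peaks together. The same value for JARID2, or for this peak alone, is not given here. Numbers are missing from the names of the JARID2 peaks around most of these high-input peaks. The lack of overlap there therefore does not show a difference in signal. At the 112 merged regions in both lists, RBP2 was 6.46 (5.75 to 7.26) and JARID2 9.55 (8.48 to 10.8) over input.

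Each IP was also raised at the peaks found only in the other list. Summed over peaks without high input, JARID2 reads were 2.30 (2.16 to 2.45) over input at RBP2-only peaks, where 200 placements matched on input coverage gave a mean of 0.9997 and at most 1.13. RBP2 reads were 2.44 (2.31 to 2.58) over input at JARID2-only peaks, against a mean of 1.03 and at most 1.16. In 500 bp windows the ratios were 1.93 (1.86 to 2.01) and 2.05 (1.98 to 2.12). The median enrichment per peak was 1.02 (1 to 1.22) for JARID2 and 1.26 (1.26 to 1.38) for RBP2. The median was exactly 1 in all 1000 random placements, because most such windows hold too few reads to move it from the added count, so it cannot measure a weak signal at this width. In 500 bp windows it was 1.40 (1.31 to 1.53) and 1.53 (1.46 to 1.57), and placements reached at most 1.02 for both.

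In the direct comparison of the IPs over 2975 merged regions, 0 regions had more RBP2 than JARID2 reads and 3 had more JARID2 than RBP2 reads. At an unadjusted p under 0.05 the counts were 18 and 387. Summed over regions without high input, RBP2 was 1.87 (1.77 to 1.97) over JARID2 at RBP2-only regions, and JARID2 was 3.21 (3.07 to 3.36) over RBP2 at JARID2-only regions, each list having been called on the reads of its own IP. Among the regions named by the rule, that on chromosome 17 from 66121809 to 66122042 held 13 JARID2 and 2 RBP2 reads, a ratio of 11.8 (2.67 to 108, adjusted p = 0.0253, exact binomial test). That on chromosome 4 from 43394618 to 43394882 held 12 and 2 reads, a ratio of 10.9 (2.42 to 100.1, adjusted p = 0.0496, exact binomial test). Those ranked 2 to 4 in this direction, each with 10 JARID2 reads and 1 RBP2 read, did not pass (adjusted p = 0.0540, exact binomial test). The region ranked first for RBP2 over JARID2, on chromosome 3 from 51287595 to 51287785, held 14 RBP2 and 0 JARID2 reads and did not pass (adjusted p = 0.177, exact binomial test). A JARID2-only region lay close beside it. The 500 bp window of the RBP2 region reaches into this neighbour. In that window, enrichment over input was 4.23 for RBP2 and 3.07 for JARID2. The JARID2 signal may come from the neighbour, so it does not show JARID2 within the RBP2 region itself. With the RBP2 library the deeper one, fewer reads are needed to pass in the JARID2 direction than in the RBP2 direction, so the counts of regions in each direction cannot be compared with each other. The counts were 17 and 623 without the shift, 0 and 55 in 500 bp windows, and 0 and 0 with the deeper IP thinned.

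Enrichment of the IPs correlated weakly. Spearman's rho was 0.10 across merged regions, but -0.50 without the shift and -0.12 in 500 bp windows, so its sign is not fixed. These regions were chosen by the reads of either IP and are not independent replicates. Across 244816 bins of 10 kb rho was 0.049 with independent parts of the input, against 0.0013 in simulated libraries without enrichment. With the whole input in both ratios it was 0.278, and 0.283 in the simulation. The observed and simulated covariances of log2 enrichment were 0.0398 and 0.0316 with the whole input and 0.0086 and 0.00051 with the independent parts.

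**Figure D3:**
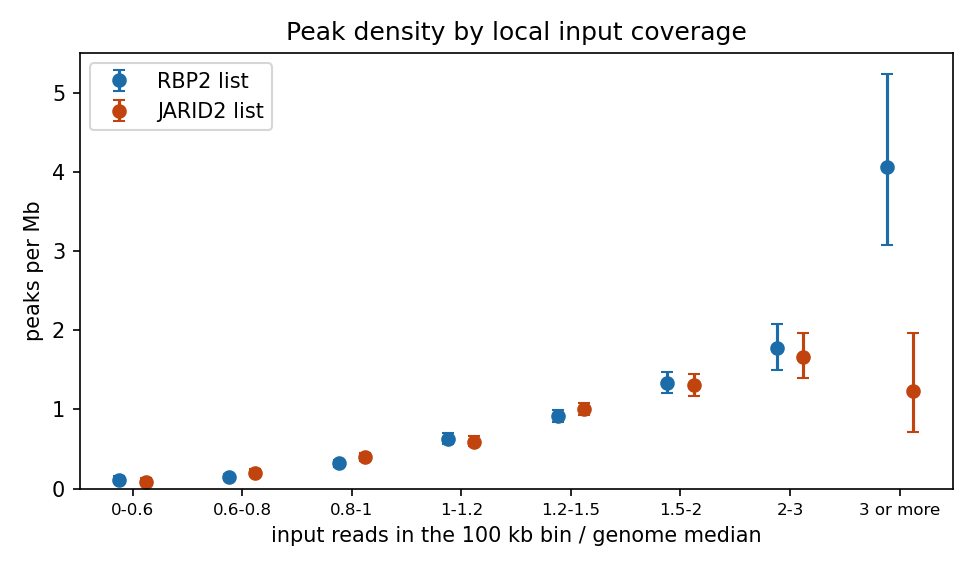
Peaks per Mb (points, with exact binomial 95% intervals) of the RBP2 and JARID2 lists in 100 kb bins grouped by input reads over the genome median. RBP2 density goes from 0.106 to 4.06 peaks per Mb, and JARID2 density from 0.0892 to 1.66 and then 1.23.

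Peaks of both lists were denser where the input coverage was higher. Below 0.6 of the median there were 0.106 RBP2 and 0.0892 JARID2 peaks per Mb. Between 2 and 3 times the median there were 1.77 and 1.66. At 3 times or more there were 4.06 RBP2 peaks per Mb (3.08 to 5.24), or 2.54 without high-input peaks, and 1.23 JARID2 peaks (0.719 to 1.97).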

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

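The mitochondrial chromosome, which no comparison used, took 0.100% of all deposited JARID2 reads (0.0979 to 0.103, exact binomial interval), above the 0.0759% of the input (0.0746 to 0.0771), while RBP2 stood at 0.0671% (0.0656 to 0.0687). These shares count duplicates. Collapsing alone left JARID2 at 0.0631% (0.0610 to 0.0651), above the input at 0.0509% (0.0499 to 0.0519), with RBP2 at 0.0501% (0.0487 to 0.0514), but it removes more of the reads on a small chromosome from a deeper library. With every library thinned to 6160334 reads and then collapsed, the JARID2 share was the same 0.0631%, the input share 0.0669% (0.0648 to 0.0690) and the RBP2 share 0.0562% (0.0544 to 0.0582), so JARID2 stood above the input with all reads and with collapsing alone, and not with both thinning and collapsing.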

How the results depend on the processing

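The windows of 100, 200, 300, 500 and 1000 bp, the placements matched on input coverage and the simulated checks were chosen after seeing the data. So were the summed reads, the libraries thinned to equal depth before collapsing, the 1 kb span of the high-input rule, the coverage classes and the segment rule. The other alternatives, among them the deeper IP thinned to the shallower, were fixed before. Of 79 alternative values, 41 stayed within the interval or within 1.5 times the count. The cause of the other shifts was not tested unless stated. Without the shift, reads in peaks were 0.218% for RBP2 and 0.187% for JARID2, median enrichments 5.05 and 5.29, peaks past the test 1413 and 1565, regions with more RBP2 or JARID2 reads 17 and 623, and rho across regions -0.50. In 500 bp windows the values were 0.211% and 0.225%, 2.996 and 3.63, 956 and 1308, and 55 regions with more JARID2 reads. The medians at the other list's peaks were then 1.40 for JARID2 and 1.53 for RBP2, and rho across regions was -0.12. Of the 5 windows looked at, JARID2 at RBP2-only peaks had a median of 1 at 100 bp, a width at which the added count fixes it (the summed reads were 2.09 over input, 1.93 to 2.26), and 1.22, 1.51, 1.40 and 1.37 at 200, 300, 500 and 1000 bp. RBP2 at JARID2-only peaks had 1.26, 1.38, 1.498, 1.53 and 1.49, and comparison with placements is uninformative at 100 and 200 bp, where their median was 1. Regions with more JARID2 reads numbered 0, 3, 139, 55 and 10 in these windows. With all deposited reads kept, 2.04% of RBP2 reads lay in RBP2 peaks, nearly all in the 40 high-input peaks, the median enrichments were 2.53 and 3.02, and rho across bins was 0.054. With a count of 5 added, the medians were 1.43 and 1.51, RBP2 at JARID2-only peaks 1.07 and rho across regions 0.18. Scaling by bins without a peak gave a median RBP2 enrichment of 2.53. Without a minimum ratio 10 regions had more JARID2 reads, and with the deeper IP thinned 0. The whole input gave rho of 0.249 across regions and 0.278 across bins, and 1 kb bins 0.0997. The higher-scoring part of each list held 798 and 783 peaks by construction, with 71 overlapping RBP2 peaks and medians of 2.70 and 3.65. Shares of peaks near a transcription start site and gene lists were not run. No paired analysis was possible because each group held 1 library. Low counts limit single peaks. With most simulated regions left unchanged, the test found 39% of 8-fold changes for RBP2 and 29% for JARID2 within peaks. At the same depth in 500 bp windows it found 86% and 79%. These shares would differ in lists where most peaks are enriched.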

Other observations

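All tests in this part were chosen after the patterns they bear on had been seen. Input coverage was uneven along the HL-1 genome. The other high-coverage segments lay on chromosome 8 from 127400001 to 128400000 at a level of 3.18, on chromosome 9 from 43900001 to 44600000 at 3.86, on chromosome 12 from 31800001, 33300001 and 39700001 at 3.11, 3.57 and 4.73, and on chromosome 14 from 25700001 at 3.27. The segment on chromosome 9 from 43900001 held 12 RBP2 and 3 JARID2 peaks in 0.7 Mb.

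Peak density rose with input coverage. Peaks made only by copy number that the input measures would hold the other IP at about the input level. In the 8 segments JARID2 was 2.31 over input at RBP2 peaks (1.99 to 2.66), and RBP2 was 2.75 over input at JARID2 peaks (2.18 to 3.49). These values are from 500 bp windows with high-input peaks kept. As sets, the peaks thus exceeded the copy number that the input measured. Peaks in both lists were not left out, and copy number missed by the input would raise both IPs alike, so the test does not decide whether copy number was left uncorrected. That the amount of DNA sets how many peaks pass the threshold remains a candidate explanation for RBP2, with a density 5.32 times that of the flanks (2.46 to 12.7), and 3.48 (1.48 to 8.79) without the segment on chromosome 9 from 43.9 Mb. These counts hold 30 RBP2 peaks in the segments, 9 of them high-input by a genome-wide limit that high coverage helps to pass, and without high-input peaks the ratio was 3.72 (1.63 to 9.23). For JARID2 the ratio was 2.30 (0.911 to 6.11), which leaves it open, although the lower bound passed 1 without either of 2 segments (1.097 and 1.02). The flanks had an input level of 1.958, against 3.875 in the segments, and held 0.672 peaks per Mb in each list. Across the genome, 100 kb bins at 1.5 to 2 times the median held 1.338 RBP2 and 1.303 JARID2 peaks per Mb. The flanks were thus sparse for their mean coverage, so both ratios may overstate the rise with coverage. The segments themselves held 3.571 RBP2 and 1.548 JARID2 peaks per Mb. More target sites per Mb in the segments may account for the higher density as well. Density also rose 2.69 times between moderate coverage classes (2.40 to 3.02), and genes were not counted here.

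The lists overlapped little. Separate places with nothing shared outside the overlapping peaks are argued against: in 500 bp windows the other IP had a median of 1.40 at RBP2-only and 1.53 at JARID2-only peaks, above the random placements, and its summed reads within the peaks were 2.30 and 2.44 over input. Weak regions near the threshold may explain part of it: 22.6% of RBP2-only peaks (20.4 to 24.9) and 26.8% of JARID2-only peaks (24.5 to 29.1) exceeded the 95th percentile of placements in the other IP, against 4.92% and 4.74% of placements. Most of these peaks did not. A signal that any IP from these cells would show stays open without a control IP, and the input at shared regions was 1.13 times the local level.

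Reads of each IP at its own peaks lay on strands less than 100 bp apart, and the tests of this were mixed. The offset of JARID2 reads at RBP2-only peaks was 101 bp (77.3 to 126). Selection of chance read clusters predicts a longer offset at the other list's peaks. This was taken over all peaks without high input, including those in both lists, which the library's own reads also chose. The difference was 28.3 bp for the JARID2 library (13.0 to 44.4), with an offset of 92.9 bp at RBP2 peaks. It was 4.85 bp for the RBP2 library (-10.2 to 21.3), which decides nothing. The first test run compared the libraries at the same peaks, and the one above replaced it after its values had been seen. The replaced comparison gave 50.2 bp at RBP2-only peaks (26.1 to 75.7) and -8.82 bp at JARID2-only peaks (-28.5 to 15.6). The second of these was not separable from 0, and comparing libraries mixes selection with fragment length. Short fragments could not be separated either, since the strand correlation was highest at a lag of 40 bp in the RBP2 library and in the input alike, close to the read length of 36 bp.

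Numbers in the names of the JARID2 peaks ran to 1664 with 99 skipped, while those of the RBP2 list had no gap. Of 30 high-input RBP2 peaks lying between a pair of JARID2 peaks, 24 (80.0%) fell in such a gap, against 95 of 1329 other RBP2 peaks (7.15%). Peaks and not gaps were counted, and some high-input peaks lay within a few kb of each other, so the 30 are not independent places. Whether JARID2 peaks were removed before deposit is not stated in the sources used here, so the 40 high-input peaks in one list against 1 in the other, and their lack of overlap, cannot be read as a difference in binding.

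Outside peaks, 608 windows of 1 kb were at least 4-fold enriched in both IPs with independent parts of the input, fewer than the 884 that independent lists would share. That value is no measure of chance here, because simulated libraries without enrichment also fell below theirs, with 264 against 925 and 203 against 725. In both cases windows without input reads or with more than 35 were left out, so no counted window lacked reads in both parts. These simulations gave 264 (236 to 287 over 10 draws) when the expected coverage was the 10 kb mean of the input, and 203 (186 to 230) when it was the window's own input. With the whole input in both ratios the count was 659, against 255 (225 to 275) and 199 (180 to 220). The levels of 2, 3 and 5-fold, which were also looked at, lay above every draw of both simulations too. The simulation draws counting error alone, so variation in coverage at a finer scale is not in it, and the cause of the excess was not tested.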
